A study of Homo sapiens with 7 samples.

How the data were processed

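The series holds 7 samples of human HepG2 cells, of which 6 have a peak list (2 each of PPARα, PPARα+ERα and PPARα+ERβ) and 1, without antibody, has none. Per the labels' protocols, chromatin was digested with a nuclease and sonicated, precipitated with an antibody to PPARα, and made into single-tube DNA libraries. Libraries 1 and 2 of each group follow the order of deposit only. The labels write the PPARα agonist as both Wy13643 and Wy14643, and it is called WY14643 here.

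The submitters' processing notes name Trim Galore 0.6.4, Bowtie 1.0.1, MACS2 2.2.7.1, HOMER 4.11, ChIPseeker 1.18.0 and DiffBind 2.16 and the builds hg38 and GRCh38.p13, without the role of each or the control used. The deposited lists give one called peak per line in narrowPeak form, with positions counted from 0 at the start. The authors' score column is 10 times the −log10 q, cut to a whole number. The authors' fold is a ratio, the enrichment of a summit over the local background that the peak caller estimated for that library. The deposited −log10 p and −log10 q are those of the summit, adjusted within a list in the case of q. Folds from different lists were not compared.

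Computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. The number of fragments at each summit and its local background were recovered from the deposited fold and −log10 p, taking fold as a ratio with 1 added above and below and p as a Poisson tail. A whole fragment number returned the deposited −log10 p within 0.001 for 100% of peaks. The lowest backgrounds of a list give its genome-wide level, and the spacing of fragments was that level set against the shortest peak width, taken as the fragment length, so it is an estimate of depth and not a read count. A site called from few fragments is known with less precision, and median stacks were 9 and 10 fragments in the PPARα+ERα lists and 35 and 50 in the PPARα lists.

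Peaks on chromosomes 1 to 22 and X that overlapped by 1 bp or more in any libraries were merged into regions, and a region was occupied in a group when both its libraries had a peak there. Group resemblance was tested by an exact one-sided permutation test over the 15 pairings of 6 libraries. Regions that differ between groups had a peak in both libraries of one and in neither of the other, and were counted again for the other 2 splits of the same 4 libraries. Chance levels came from 100 circular shifts of a list along each chromosome, by at least 1 Mb. Shifted peaks were not kept out of stretches where none can be called, so these levels may be too low. Shares carry Wilson 95% intervals, which cover counting error only. Shares of regions and lists were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over all lists and groups, or over all comparisons, at 0.05 (for differing regions, among genes with a region near an end in any library compared), and library means by an exact two-sided permutation test.

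The available annotation, a gene table of GRCh38.p14, has no strand, exons or sequence. Transcription start sites were therefore replaced by either end of a gene's span, and near means within 3 kb of an end. Exon classes, the check of plasmid coding exons, the 14 motifs planned at summits and their alternatives were not run. The 21 gene lists were fixed before the data were examined. Of their 564 symbols, 561 matched the table and 3 did not, and the lists take in fatty acid oxidation, lipid handling, lipoproteins, estrogen response, thermogenesis, oxidative phosphorylation, cGMP signalling, nuclear receptors, hepatocyte, bile acid, cholesterol, fatty acid synthesis, glucose, stress, circadian, ribosomal, histone, adipocyte, neuron, muscle and blood genes.

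Genes were named by a rule fixed before the data were examined. It takes PPARA, ESR1 and ESR2, the 12 protein-coding genes per comparison and direction whose differing region ranked highest by the lower of its within-list percentiles of −log10 q, the 10 ranked so over regions in all 6 libraries, and up to 4 members per list that differ, or that are occupied in all groups or in none. Not every gene the rule names is reported. GADD45GIP1 and FST, and the regions named only among the closing observations, were chosen after their values were seen.

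The steps were tested on simulated data of known outcome. All of 1850 simulated fragment numbers were recovered, and so were 100% of 200 planted regions among 12000 in each comparison. Unplanted regions were also counted as differing through chance detection, 530, 533 and 541 in the 3 comparisons where 520.4 were due, so a differing region is not by itself a difference in binding. With 40% of a list's genes occupied against 6% of others, 93% of 100 planted lists were called, and 5 unplanted lists were called. In the data, the highest share of a list occupied near gene ends was 17.6%, for circadian genes with PPARα+ERβ. Detection at such lower shares was not simulated. Alternatives fixed before the data were examined were a stricter q, equal list lengths, all sequences, peaks trimmed to 100 bp each side of the summit, peaks up to 500 bp apart merged, a 1 kb window, the nearest gene end within 50 kb, and leaving out each library. The others were added after seeing the data, namely low-background peaks, the strongest peaks of each list, and a region anywhere in a gene span.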

Results

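Binding of PPARα, the fatty-acid-sensing nuclear receptor that drives lipid catabolism genes in liver, was mapped by chromatin immunoprecipitation and sequencing in HepG2 cells, a line derived from a human hepatocellular carcinoma. Cells carried a PPARα expression vector alone or together with a vector for the estrogen receptor ERα or ERβ, and all received the PPARα agonist WY14643 at 10 µM for 2 h, with agonists given from 48 h after transfection. The PPARα+ERα cells were first exposed for 45 min to PPT, an ERα-selective agonist, at 10 nM, and the PPARα+ERβ cells for 45 min to DPN, an ERβ-selective agonist, at 10 nM. Each of the 3 groups held 2 libraries, which the labels do not describe as separate cultures. Every SD and every permutation p given here therefore measures variation between these libraries only, and that variation may be technical. Fisher's exact tests take regions or genes as units and do not measure variation between libraries. The series as a whole concerns how weight loss through PPARα activation by PDE9 inhibition depends on sex, and these libraries ask where PPARα binds with and without each estrogen receptor. The no-antibody sample had no peak list and was not analysed here.

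On chromosomes 1 to 22 and X, the authors' peak lists held 23805 and 36302 peaks in the PPARα libraries, 24505 and 27544 in the PPARα+ERα libraries, and 17457 and 23302 in the PPARα+ERβ libraries. The group means were 30053.5 ± 8837, 26024.5 ± 2149 and 20379.5 ± 4133 peaks (SD, n = 2). Sequencing totals were not analysed here, so depth was read from the lists themselves, as the genome-wide spacing of fragments that the peak caller's background implies. That spacing was 537 and 471 bp per fragment for PPARα, 779.7 and 725 bp for PPARα+ERα, and 537 and 449.8 bp for PPARα+ERβ, which makes the PPARα+ERα libraries the shallowest. The groups also differed in the kind of site called. The median peak rose from a local background 14.6 ± 1.55 times the genome-wide level with PPARα, 1.60 ± 0.0557 times with PPARα+ERα and 8.93 ± 0.579 times with PPARα+ERβ (SD, n = 2). The median number of fragments stacked at a summit was 35 and 50 with PPARα, 9 and 10 with PPARα+ERα, and 27 and 29 with PPARα+ERβ.

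**Figure D1:**
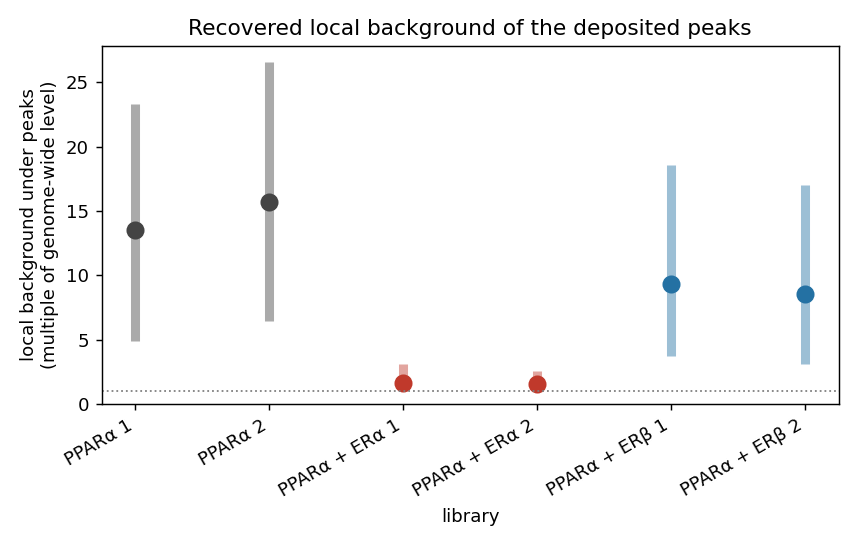
Local background under the called peaks of each library, as a multiple of that library's genome-wide level, with points for the median, bars from the lower to the upper quartile and a dotted line at 1. The PPARα+ERα medians lie at 1.64 and 1.57, below the lower quartile of each of the other 4 libraries.

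The transfected genes themselves were examined first, since plasmid DNA could leave peaks over their coding sequence. The span of PPARA held 2 and 4 peaks in the PPARα libraries, 1 and 2 with PPARα+ERα and 1 and 3 with PPARα+ERβ. The span of ESR1, the ERα gene, held 3 and 6, 3 and 6, and 4 and 4 peaks in the same order. ESR2, the ERβ gene, held a single peak, in PPARα+ERα library 1 (chromosome 14, 64296052 to 64296356). These counts did not follow the plasmids, and without exon positions no peak could be assigned to coding sequence. A PPARA region at 46194240 to 46194583 on chromosome 22 had peaks in both PPARα and both PPARα+ERβ libraries. In ESR1, a region ending at 151670777 on chromosome 6 had peaks in both PPARα+ERα libraries (fold 5.403 and 5.62) and both PPARα+ERβ libraries (fold 7.44 and 5.57) and in neither PPARα library. Here and below, fold is the authors' own enrichment of a summit over its local background, and it ranks peaks within a list only.

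PPARα+ERα libraries shared few peaks with those of the other groups, as at COG4 and NOP56 below, while PPARα and PPARα+ERβ libraries shared many, as at TLL1 and CCNE2. Merging overlapping peaks gave 92292 regions. Here and below, bound means only that a peak was called. Whether PPARα itself holds these sites was not tested, as no motifs were run. The Jaccard index, the share of regions bound in either library that were bound in both, was 0.414 between the PPARα libraries, 0.205 between the PPARα+ERα libraries and 0.334 between the PPARα+ERβ libraries. Between groups it averaged 0.313 for PPARα with PPARα+ERβ, 0.0310 for PPARα+ERα with PPARα+ERβ and 0.0163 for PPARα with PPARα+ERα. PPARα library 1 and PPARα+ERβ library 2 shared more (0.357) than the PPARα+ERβ libraries did with each other. The labelled pairing gave the highest mean within-pair index of the 15 ways to pair 6 libraries, 0.318 against 0.282 for the next (exact permutation test, one-sided p = 0.0667, the smallest that 15 pairings allow). Few shared regions still exceeded chance: 3.84% of peaks of PPARα library 1 overlapped PPARα+ERα library 1, against at most 0.769% in 100 shifted copies.

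**Figure D2:**
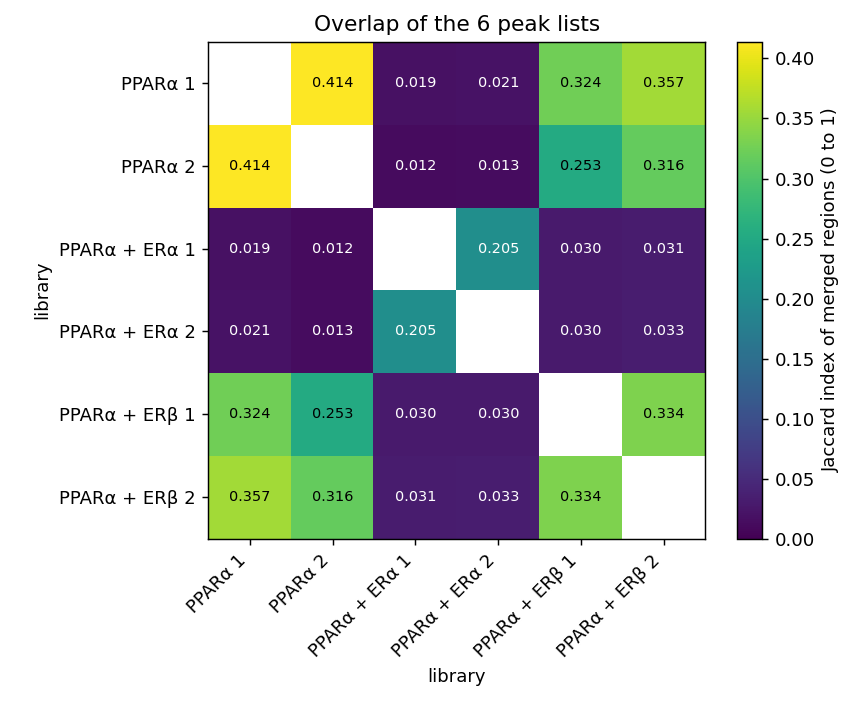
Jaccard index of bound regions for each pair of the 6 libraries, with brighter cells for more shared regions and the diagonal left blank. PPARα and PPARα+ERβ libraries share 0.253 to 0.357 across groups, and PPARα+ERα libraries share at most 0.0328 with any library of another group.

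Peaks common to all 6 libraries lay in 123 regions and near the ends of 23 protein-coding genes. They included MLXIP, a glucose-responsive transcription factor that partners MLX (chromosome 12, 122078184 to 122078621), with fold 5.18 and 7.86 in PPARα, 5.71 and 4.96 in PPARα+ERα and 8.78 and 8.45 in PPARα+ERβ libraries. POLR3K, a subunit of RNA polymerase III, shared a region with SNRNP25 (chromosome 16, 52449 to 53150; fold 8.87 and 6.94, 21.6 and 22.0, and 7.01 and 7.70 in the same order). CCNYL1 (chromosome 2, 207751856 to 207753269) had fold 10.7 and 17.9, 10.8 and 7.75, and 8.20 and 12.9. The other genes ranked highest were C6orf52, KCTD13, DAZAP2, ACKR2, DYNC2LI1 and PRICKLE1, a planar cell polarity gene. Occupied regions, those with a peak in both libraries of a group, numbered 17597 for PPARα (41.4% of the regions found in either library), 8866 for PPARα+ERα (20.5%) and 10204 for PPARα+ERβ (33.4%). PPARα and PPARα+ERβ shared 6521 of these, PPARα+ERα and PPARα+ERβ 307, and PPARα and PPARα+ERα 165. Of the regions occupied by PPARα+ERα, 89.8% had no peak in any other library, compared with 30.4% for PPARα and 11.1% for PPARα+ERβ. Single libraries gave far more: 36299 for PPARα without its library 1, 27541 and 24501 without PPARα+ERα library 1 and 2, and 23295 and 17454 without PPARα+ERβ library 1 and 2, with 396 and 333 regions in all 3 groups without PPARα+ERα library 1 and 2. Taking lists of equal length gave 9764 for PPARα, 5845 for PPARα+ERα and 37 for all 3 groups, and only low-background peaks, a choice made after seeing the data, gave 2223 for PPARα, 2117 for PPARα+ERβ and 78 for all 3, while a stricter q gave 79 for all 3.

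The comparison of PPARα+ERα with PPARα asks where binding differs with ERα present. Its top region lay in COG4, a Golgi tethering subunit, close to SF3B3, a splicing factor (chromosome 16, 70523160 to 70523642), with fold 32.9 and 33.5 in the PPARα+ERα libraries and no peak in the other 4 libraries. Others bound in both PPARα+ERα libraries were in PSMD1, a proteasome subunit (fold 17.2 and 18.4), NOP56, a ribosomal RNA processing factor (fold 20.1 and 28.2), MMD (fold 16.6 and 16.1), the mitochondrial ribosomal gene MRPL30 near MITD1 (fold 15.4 and 17.8), and the overlapping genes PSME3IP1 and RSPRY1 (fold 15.8 and 21.8). A region in XPNPEP3, near DNAJB7 and ST13 (chromosome 22, 40856967 to 40857382), was bound with PPARα+ERα (fold 9.06 and 9.19) and also with PPARα+ERβ (9.69 and 8.29). The PPARα regions without a PPARα+ERα peak included TLL1, a protease that matures procollagen (chromosome 4, 166105045 to 166105518; fold 20.5 and 26.5), RBM6 (8.20 and 10.1), a region in NEK8 near TRAF4 (12.2 and 16.9) and the cell cycle gene CCNE2, encoding cyclin E2 (13.3 and 16.8). IMPG1, GCA, CTBS, OR56A4, MTUS1, CLEC4D and MAK were the other genes that ranked highest. All 12 of these PPARα genes also had peaks in both PPARα+ERβ libraries.

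Fatty acid oxidation genes appeared on both sides of that comparison. Of the 30 in the list, 11 had a region near an end in any of the 4 libraries, 4 of them a PPARα+ERα region and 3 a PPARα region. Of the 6555 other genes with a region, 918 and 1407 did, and neither share of the list passed Fisher's exact test (two-sided, unadjusted p = 0.0564 and 0.712). ACADM, the medium-chain acyl-CoA dehydrogenase (fold 4.66 and 5.05), HADHA, the trifunctional protein subunit (8.86 and 8.01), and ETFA, which takes electrons from the dehydrogenases (8.83 and 8.08), had PPARα+ERα regions. ACAA2, a thiolase (6.97 and 4.401), and SLC25A20, the carnitine-acylcarnitine carrier (5.73 and 12.5), had PPARα regions. ACADL had one of each, at 210190577 to 210190938 and at 210226810 to 210227319 on chromosome 2. Regions on either side also lay near lipoprotein genes (SCARB1 with PPARα+ERα, APOM with PPARα), the fibrinogen genes FGG with PPARα+ERα and FGB with PPARα, and cGMP signalling (PRKG1 with PPARα+ERα, NPR1 and CORIN with PPARα). The coactivator genes MED1 (fold 11.2 and 14.9) and NCOA2 (6.49 and 5.78) and the pioneer factor FOXA1 (8.29 and 8.19) had PPARα+ERα regions. No list passed the test on either side of this comparison, and the RBM6 peaks with PPARα stood on a local background 17.2 and 16.9 times the genome-wide level, those of COG4 on 2.43 and 2.39 times. Other top regions went against that contrast. The TLL1 peaks with PPARα stood on 3.11 and 3.09 times, and the XPNPEP3 peaks with PPARα+ERα on 30.8 times in both libraries.

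In all, 8434 regions were bound in both PPARα+ERα and neither PPARα library, and 16724 the reverse, a sum of 25158 compared with 455 and 451 for the other 2 ways of splitting the same 4 libraries into pairs. These regions lay near the ends of 922 and 1410 genes. No p is given, because 4 libraries allow only 3 splits. The direction turned to 6632 and 1740 when only peaks with a local background up to 3 times the genome-wide level were kept, a choice made after seeing the data, and lists of equal length gave 9554 for PPARα. Regions bound with PPARα+ERα alone rose to 26236 and 23328 without PPARα+ERα library 1 and 2, and those with PPARα alone to 34992 without PPARα library 1.

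**Figure D3:**
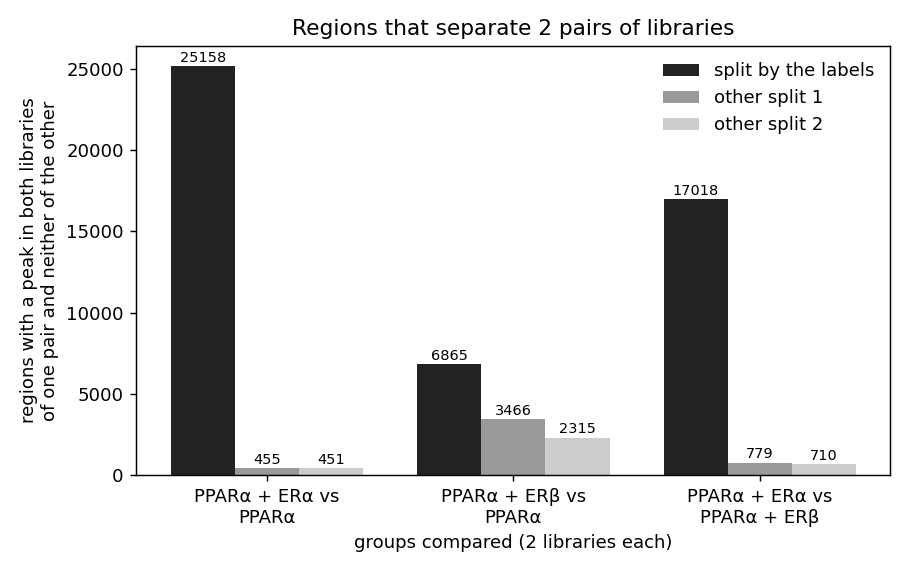
Number of regions bound in both libraries of a pair and in neither library of the other pair, for the labelled split of each comparison and the other 2 splits of the same 4 libraries. The labelled split gives 25158, 6865 and 17018 regions, above each of its alternatives.

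The comparison of PPARα+ERβ with PPARα asks the same of ERβ. Regions bound in both PPARα+ERβ libraries and neither PPARα library were led by the XPNPEP3 region and by EIF2S3, a translation initiation subunit (chromosome X, 24054533 to 24055004; fold 16.3 and 17.3), which also had PPARα+ERα peaks (7.99 and 12.4). ZMAT1 (17.0 and 16.4), PRRC2C (12.4 and 12.2), GPCPD1, a choline metabolism enzyme (7.46 and 8.21), and SEC14L1 followed. So did ZNF487, BICRA, SUPV3L1 and NDUFA10, a subunit of respiratory complex I (8.80 and 6.83). NDUFA10 also had peaks in both PPARα+ERα libraries (5.28 and 4.77), ZMAT1 in library 2 alone and SUPV3L1 in library 1 alone. The circadian repressors PER2 (chromosome 2, 238245043 to 238245507; fold 11.03 and 8.43) and PER1 (3.34 and 3.14), the fatty acid oxidation enzyme gene ECH1 (3.72 and 4.96) and the cGMP phosphodiesterase gene PDE1A (5.33 and 4.76) were on the same side. The reverse set held DDX60, an interferon-induced helicase (chromosome 4, 168219293 to 168219703; fold 9.19 and 8.61), TMEM135 (4.24 and 5.50), BAMBI, a decoy receptor for TGF-β (4.05 and 4.85), WWTR1, the Hippo pathway coactivator TAZ (4.33 and 5.00), and IL1RL2, SLC35A3, ANTXR1, NOSTRIN, DPH5, B4GALT3 and PPOX. It also held COX7A1 (4.63 and 9.13), PNPLA3 (4.13 and 5.04) and the unfolded protein factor XBP1 (3.35 and 2.88), and none of these 3 regions had a PPARα+ERα peak.

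The counts were 1454 regions with PPARα+ERβ and 5411 with PPARα, near 196 and 385 genes, a sum of 6865 compared with 3466 and 2315 for the other 2 splits. With low-background peaks alone the direction turned, to 486 and 399, and their sum of 885 stood beside 809 and 523 for the other splits, while lists of equal length gave 2264 and 2788. The PPARα+ERβ count was 2408 and 2729 without PPARα library 1 and 2, and 6920 and 4883 without PPARα+ERβ library 1 and 2, and the PPARα count was 18931, 8785 and 9214 without PPARα library 1, PPARα library 2 and PPARα+ERβ library 2.

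The co-transfected groups were also compared with each other. PPARα+ERα regions without a PPARα+ERβ peak were led by COG4 and SF3B3, PSMD1, NOP56, MITD1 and MRPL30, and PSME3IP1 and RSPRY1, with GHDC (fold 15.8 and 16.2), the proteasome gene PSMD12 (chromosome 17, 67365186 to 67365525; fold 13.5 and 14.9), the splicing factor gene SF3B1 (chromosome 2, 197432867 to 197433307; fold 15.1 and 16.9) and TXNDC11 (4.38 and 4.53). PPARα+ERβ regions without a PPARα+ERα peak included HMGA2, an architectural chromatin protein (chromosome 12, 65826782 to 65827137; fold 9.28 and 9.19), SPRY1, an inhibitor of growth factor signalling (6.58 and 6.88), CCNE2 and NDUFAF6 (14.5 and 12.8), CNFN (17.7 and 18.1) and the centrosome gene CEP250 next to C20orf173 (12.8 and 9.59). TBC1D12, GGT7, OR6S1, CTBS and GPCPD1 were the other genes that ranked highest. SPRY1, CCNE2, NDUFAF6, CNFN, TBC1D12, GGT7, CTBS, C20orf173 and CEP250 also had peaks in both PPARα libraries. HMGA2 and OR6S1 had one in PPARα library 2 only, and GPCPD1 in neither. The counts were 8062 and 8956 regions, near 862 and 932 genes, a sum of 17018 compared with 779 and 710 for the other splits. Low-background peaks alone gave 6368 and 1399, the opposite direction. That filter kept 74.3 and 76.9% of PPARα+ERα peaks and 21.7 and 24.8% of PPARα+ERβ peaks, so unequal loss may give the turn. Without PPARα+ERα library 1 and 2 the first count was 25437 and 22567, and without PPARα+ERβ library 1 and 2 the second was 20832 and 15435.

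Both comparisons with PPARα alone used the same PPARα libraries, so regions counted in both are linked by that shared control. Regions with peaks in both PPARα libraries and in no co-transfected library, such as DDX60 and COX7A1, numbered 5356, which is 98.98% of those absent with PPARα+ERβ. Within the 17597 regions occupied with PPARα, independent losses would already share 5143, since most of these regions lacked a PPARα+ERα peak. A simulation with unchanged binding gave a shared 2.85%, a value set by its assumed rate of detection, equal for both co-transfected groups. PPARα+ERα lists held a peak in at most 4.34% of the regions of a PPARα list, so the simulation is no baseline for these losses. Regions with peaks in all co-transfected and no PPARα libraries numbered 95, which is 6.53% of the PPARα+ERβ set. The same simulation gave 2.75%, whereas independent gains among the 49791 regions without a PPARα peak would share 246, so no excess or deficit is claimed. Beyond XPNPEP3 and EIF2S3, these included GADD45GIP1, a mitochondrial ribosome factor (chromosome 19, 12957187 to 12957580), and FST, the activin antagonist follistatin (chromosome 5, 53481472 to 53481854; fold 7.71 and 8.66 with PPARα+ERα, 4.86 and 4.93 with PPARα+ERβ). The 2 control libraries were not divided between the comparisons, as that would leave a single PPARα library for each and an occupied region asks for both.

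Many of the strongest peaks of the co-transfected libraries lay near the ends of genes, such as COG4, NOP56, EIF2S3 and XPNPEP3. Among all peaks, 12.8% ± 0.521 of summits with PPARα, 13.8% ± 0.0281 with PPARα+ERα and 14.1% ± 0.236 with PPARα+ERβ lay within 3 kb of either end of a gene (SD, n = 2), where shifted copies gave 12.09, 12.01 and 12.17%. Among the strongest 1000 peaks of each list, a choice made after seeing the data, the shares were 11.3 and 13.2% with PPARα, 22.4 and 24.9% with PPARα+ERα, and 16.9 and 18.7% with PPARα+ERβ. The Wilson 95% intervals, which cover counting error only, ran from 9.48 to 15.4%, 19.9 to 27.7% and 14.7 to 21.2% over the libraries of each group. The highest of 100 shifted copies reached 15.4%. Over all peaks, PPARα library 1 (12.44%) stayed below its highest shifted copy (12.52%), and the other libraries exceeded theirs. Each pairwise difference, among all peaks and among the strongest 1000, gave p = 0.333 by an exact two-sided permutation test, the smallest that 2 against 2 libraries allow. Among the strongest 1000 low-background peaks the shares were 11.5 and 13.6%, 19.4 and 20.1%, and 13.3 and 14.4%, so PPARα and PPARα+ERβ libraries overlapped there, and this was not tested. Regions bound with PPARα+ERβ and not PPARα lay near gene ends more often than the reverse set, 17.6 against 11.9% (Fisher's exact test, two-sided, odds ratio 1.58, adjusted p = 7.36e-08), as did those of PPARα+ERα, 15.3 against 13.4% (odds ratio 1.17, adjusted p = 4.10e-05), with regions and not libraries as the units. The PPARα+ERα and PPARα+ERβ regions did not differ detectably, 15.3 against 15.4% (Fisher's exact test, adjusted p = 0.848). A window of 1 kb gave 4.38, 5.00 and 5.08% of all peaks in the order above.

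**Figure D4:**
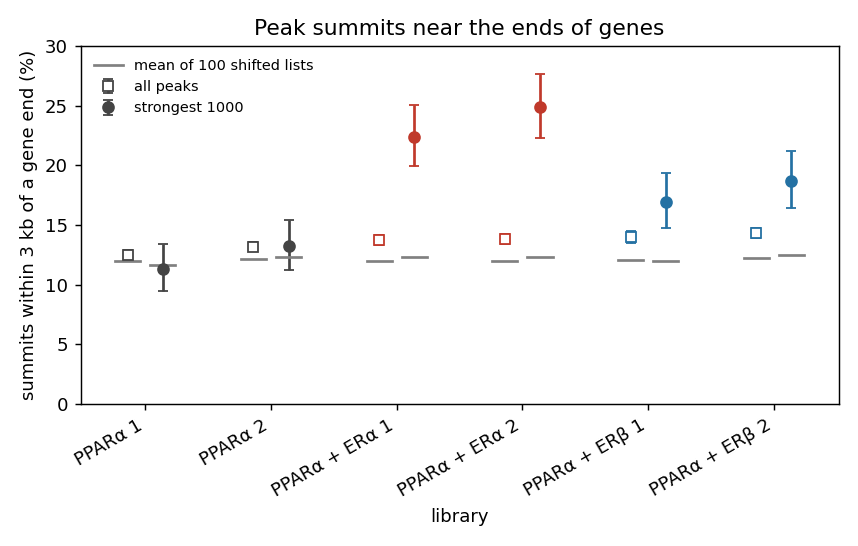
Share of summits within 3 kb of a gene end in each library, for all peaks (open squares) and the strongest 1000 (filled circles), with Wilson 95% intervals and grey lines at the mean of 100 shifted copies. For the strongest 1000, PPARα libraries sit at 11.3 and 13.2%, and the co-transfected libraries between 16.9 and 24.9%.

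Occupancy near gene ends was counted for each fixed list. Among known PPARα targets, ANGPTL4, CPT2 and ACADVL had none in any library, and CPT1A, FGF21 and PLIN2 had a peak in 1 library each. Of 30 genes of fatty acid oxidation, 3 were occupied with PPARα, 4 with PPARα+ERα and 3 with PPARα+ERβ (Fisher's exact test, two-sided, unadjusted p = 0.487, 0.0564 and 0.221), and of 34 genes of PPARα lipid handling, 3, 1 and 3, among them MBL2, IMPA2 and TSKU. Of 40 estrogen response genes 2, 1 and 1 were occupied, with no peak at GREB1 or TFF3 in any library. The remaining lists gave, in the same order of groups, 1, 2 and 0 of 19 lipoprotein genes, 2, 1 and 0 of 21 thermogenic genes, 0, 2 and 0 of 35 oxidative phosphorylation genes (UQCRC2 and COX5B), 2, 1 and 2 of 21 genes of cGMP signalling, and 0, 2 and 1 of 35 nuclear receptors and coregulators. Metabolic lists gave 2, 4 and 1 of 34 hepatocyte genes, 0, 0 and 1 of 28 bile acid and xenobiotic genes, 3, 1 and 2 of 24 cholesterol synthesis genes, 2, 0 and 0 of 21 fatty acid synthesis genes (THRSP and PNPLA3) and 2, 4 and 1 of 28 glucose metabolism genes. Immediate early and stress genes gave 2, 2 and 2 of 30, circadian genes 2, 0 and 3 of 17, ribosomal protein and other highly expressed genes 4, 4 and 2 of 40 and core histones 2, 1 and 5 of 30. Markers of other cell types gave 1, 0 and 1 of 14 for adipocytes, 2, 1 and 1 of 18 for neurons, 1, 1 and 1 of 20 for skeletal muscle and 2, 1 and 1 of 22 for blood cells.

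Across all 19974 protein-coding genes, 7.45% were occupied with PPARα, 4.88% with PPARα+ERα and 5.43% with PPARα+ERβ. In each group, 0 of the 21 lists passed Fisher's exact test (SciPy, Benjamini-Hochberg; lowest adjusted p = 0.981, 0.966 and 0.966). The highest list share was 17.6%, and detection had been simulated only at 40%, so smaller enrichments could have been missed. Adjusted over the list alone, that is within each group's 21 lists, 0 passed Fisher's exact test as well, and at an unadjusted p under 0.05 there were 0, 1 and 1, glucose metabolism with PPARα+ERα (ALDOA, TPI1, PKLR and PCK2, p = 0.0455) and core histones with PPARα+ERβ (p = 0.0214), where H2AC6 and H2BC4 share a region and count as separate genes. ACADL and LYZ, a myeloid marker, were the only list members occupied in all 3 groups, with PPARα and PPARα+ERβ peaks in the same regions and PPARα+ERα peaks elsewhere. For the regions that differed between groups, tested among genes with a region near an end in any of the 4 libraries compared, 0 lists passed Fisher's exact test in any direction of the 3 comparisons, and 2 had an unadjusted p under 0.05, oxidative phosphorylation with 0 of 17 genes on the PPARα side against PPARα+ERα (p = 0.033) and core histones with 2 of 7, H2AC16 and H3C4, on the PPARα+ERβ side against PPARα (p = 0.0338). Counting a region anywhere in a gene's span, a choice made after seeing the data that does not correct for gene length, passed 4 lists with PPARα (immediate early and stress, ribosomal, core histone and blood cell genes) and 1 with PPARα+ERβ (ribosomal), each occupied less often than other genes.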

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

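Among the tests reported here, those of depth without a call model, of chance stacks, of separate handling, of low-background peak numbers, of another control library and of dense-background peaks behind the PPARα+ERβ excess were chosen only after the result was seen. A mitochondrial peak over RNR2, the 16S ribosomal RNA gene, stood in both PPARα+ERα libraries, outside the chromosomes compared, with 16 fragments at its summit in library 1 (positions 2449 to 2856) and 13 in library 2 (positions 2455 to 2776), and the other 4 libraries had 0 mitochondrial peaks.

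The first pattern is the small number of regions, 165 with PPARα and 307 with PPARα+ERβ, that PPARα+ERα shares with the other groups. Lower depth is argued against as the whole cause, since at most 5.87% of the peaks of a PPARα+ERα list are found in any of the deeper lists, against at least 32.2% in the other PPARα+ERα list. PPARα stacks scaled to PPARα+ERα depth predict 1.74% of the regions without a PPARα+ERα peak, but that model overstates recall within groups, most in PPARα+ERα (87.2% predicted, 32.2% observed for library 2 in library 1), and is not relied on. Chance stacks that arise separately in each library are argued against by the same 32.2%, against at most 0.755% in shifted copies. The shifts cannot address stacks common to both libraries, which may be technical repeats. Separate handling of these libraries could account for the pattern and cannot be told apart from ERα co-transfection. Both libraries stand apart together (highest index with another group 0.0328), and the labels name no batch that crosses the groups. An effect of ERα and its agonist stays open too.

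The second pattern is that PPARα and PPARα+ERβ peaks lie where the background is dense, while PPARα+ERα peaks do not. Greater depth should add peaks and not remove those on a low background, yet the deeper lists hold at most 31.7% as many low-background peaks as the smaller PPARα+ERα count (5776 against 18195). An earlier test on PPARα peaks callable at PPARα+ERα depth decided nothing, as it kept 95.4% of library 1 and left its median background at 13.5. Another control library is argued against, since the spacing of control fragments recovered from the 6 lists differs by at most 1.42%. How the chromatin was digested and handled could differ by group and was not tested, and neither was a biological effect of ERα.

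The third pattern is the higher share of gene ends among the strongest co-transfected peaks. Whether dense-background sites crowd out such peaks in PPARα is not settled for the PPARα+ERα excess. The strongest 1000 low-background peaks are drawn from 3818 and 4639 in PPARα and 18195 and 21175 in PPARα+ERα, which are unlike fractions. Low-background PPARα peaks reach 11.5 and 13.6%, little above the 11.3 and 13.2% over all backgrounds, against 19.4 and 20.1% with PPARα+ERα. They also stay below 16.9%, the lowest co-transfected library, but that share takes all backgrounds and is an unlike set. Low-background PPARα+ERβ peaks reach 13.3 and 14.4%, so for that group the test decides nothing. The pattern did not vanish with the strongest 500 or 2000, where the smallest gap was 3.85 percentage points. Its size depends on rank, as over all peaks the highest PPARα library reached 13.2% and the lowest co-transfected library 13.8%. A few regions shared by the co-transfected groups are argued against by a gap of 4.1 points without them. For PPARα+ERβ alone, dense-background peaks may carry the excess, as the gap was -0.3 points among low-background peaks. The PPARα+ERα excess (19.4 and 20.1% among low-background peaks) was not traced to a source. ERα co-transfection with its agonist, the separate handling above and crowding by dense-background sites remain candidates. Others, such as depth, were not tested for this pattern.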

How the results depend on the processing

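The values for low-background peaks, for the strongest peaks and for a region anywhere in the gene span were chosen only after the result was seen. Of the values under alternatives, set against 41 reported ones, 117 stayed and 49 moved. Staying meant counts within 1.5 times, shares near gene ends within 1 SD between libraries, and the overlap within groups above the mean of other pairings or, with a library left out, of other groups. Only that overlap could be labelled reversed, and it was so in 0 cases. Counts, shares and numbers of lists could only stay or move, so their direction was not judged. A pair of opposite counts can change order, as with low-background peaks. With 2 libraries per group, the share near gene ends stays by construction when a library is left out. The cause of a move was not tested unless fewer peaks or libraries give it by construction. A stricter q gave 79 regions in all 3 groups and 14.3% of PPARα+ERα peaks near gene ends. Lists of equal length gave 9764 occupied regions for PPARα, 5845 for PPARα+ERα and 37 for all 3, with 9554 PPARα regions against PPARα+ERα, and 2264 PPARα+ERβ and 2788 PPARα regions in their comparison. Low-background peaks gave 2223 for PPARα, 2117 for PPARα+ERβ and 78 for all 3, then 1740 PPARα regions against PPARα+ERα, 486 PPARα+ERβ and 399 PPARα regions, and 1399 PPARα+ERβ regions against PPARα+ERα. The share near gene ends in PPARα, PPARα+ERα and PPARα+ERβ was 4.38, 5.00 and 5.08% within 1 kb, 11.9, 25.9 and 19.1% for the strongest 500 peaks, 12.25, 23.65 and 17.8% for the strongest 1000, and for the strongest 2000 it was 20.25% with PPARα+ERα and 17.2% with PPARα+ERβ. A region anywhere in the gene span passed 4 lists with PPARα and 1 with PPARα+ERβ, all occupied less often than other genes, and 0 with PPARα+ERα. Leaving out each library gave 23799 to 36299 occupied regions for PPARα, 24501 to 27541 for PPARα+ERα, 17454 to 23295 for PPARα+ERβ and 135 to 396 for all 3. For PPARα+ERα and PPARα it gave 8525 to 26236 and 17027 to 34992 regions, for PPARα+ERβ and PPARα 2408 to 6920 and 7273 to 18931, and for PPARα+ERα and PPARα+ERβ 8272 to 25437 and 9373 to 20832. The mean overlap within groups ranged from 0.270 to 0.374 and the number of lists past the test stayed at 0, with the share near gene ends at 12.4 to 13.2, 13.76 to 13.80 and 13.98 to 14.3%. Peaks trimmed to the summit or merged across 500 bp moved none of the results they were run for. No paired analysis was possible because the library numbers give the order of deposit only. Not run for want of sequence, strand and exons were the 4 motif alternatives and the exon classes of the transfected genes. Depth limits what a missing peak shows, since a site may fall short of the authors' threshold, as with the 79 regions left under a stricter q. Counting error on a single site is largest in the PPARα+ERα lists, whose median peaks hold 9 and 10 fragments on a low background.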

Other observations

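The comparisons of chromosomes, of peak edges and of pairs of libraries given here were all chosen only after the results were seen. Some of the strongest regions common to all 6 libraries lay inside genes and away from their ends. MAPT, the gene of the microtubule protein tau, held one (chromosome 17, 45903716 to 45904399) with fold 21.4 and 48.7 in PPARα, 11.9 and 18.6 in PPARα+ERα and 19.7 and 30.5 in PPARα+ERβ libraries. ARL6IP6 (chromosome 2, 152753139 to 152753715) and DCBLD1 (chromosome 6, 117514594 to 117515036) held others. Of the regions occupied in both co-transfected groups, one at the chaperonin gene CCT4 and COMMD1 (chromosome 2, 61888486 to 61889217) ranked next to C6orf52, with fold 13.1 and 12.3 with PPARα+ERα, 12.1 and 12.5 with PPARα+ERβ and a peak of fold 2.70 in PPARα library 2 alone.

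Peaks of PPARα+ERα were spread over the chromosomes differently from those of PPARα. Chromosome 2 held 12.4% ± 0.271 of PPARα+ERα peaks and 9.77% ± 0.730 of PPARα peaks, chromosome 20 held 3.92% ± 0.242 and 2.83% ± 0.0684, and chromosome X held 1.395% ± 0.104 and 2.79% ± 0.239 (SD, n = 2). Chromosomes 14 and 16 held 4.05 and 3.99% of PPARα+ERα peaks against 3.55 and 3.49% of PPARα peaks. Chromosomes 19 and 22 went the other way, with 1.81 and 1.06% against 2.60 and 1.33%. These shares were not corrected for the copy number of each chromosome, which both groups share as 1 cell line. The source of the differences was not tested, so they do not by themselves show a shift in binding.

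Between overlapping peaks of PPARα and PPARα+ERβ libraries, 42.5 to 45.8% began at the same base, and between the PPARα+ERα libraries 40.4%, against 23.1 to 32.1% between PPARα+ERα and other libraries. Of all choices of 2 libraries, the PPARα+ERα pair was absent from the most regions bound in the other 4, 5915, followed by the PPARα pair with 95. The PPARα+ERβ pair was absent from 10, fewer than any pair drawn from different groups (13 to 78).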
